A study of Bos taurus with 56 samples.

How the data were processed

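RNA of the Longissimus dorsi, the long muscle of the back, was sequenced from bulls of the Nguni breed (Sanga) and the Bonsmara breed (Sanga-related) that were kept in a feedlot for 120 days on a diet of high energy (12.0 MJ of metabolizable energy per kg) or of low energy (10.9 MJ per kg). Per the labels' protocols, the muscle was frozen in liquid nitrogen, RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit. The submitters' processing notes name Trimmomatic, FastQC, Salmon and DESeq2, with no version and no role. The genome build, the annotation release and the strand setting are not given in the sources used here.

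The values used are the gene-level estimated counts that the authors deposited in 4 tables, one for each pair of groups that share a breed or a diet. They are taken to be estimated and not direct counts because the notes name Salmon and because 48 of the 54 values with 7 or more digits end in 0, as numbers stored with limited precision do. All were whole numbers as deposited, so rounding them to whole numbers moved none. The tables list 20791 Ensembl bovine gene IDs for 42 libraries. Each library stands in 2 tables, and the 2 columns were identical for all 42, so each was taken once. The labels describe 56 samples, of which 14 were not analysed here.

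Groups came from the breed and diet in the labels. Titles join a stem and a suffix (B6_1, B6_2, B6_3), and the 42 libraries share 14 stems with 3 libraries each. A stem was read as an animal, which the labels do not state, and the 3 libraries of a stem were summed, so n counts stems. If stems are not separate animals, the p-values measure only the spread between these samples, which may be technical. The labels and the tables disagree on 2 stems: N1 is labelled low energy and stands in the tables with the high energy Nguni, and N11 is labelled high energy and stands with the low energy Nguni. The labels were followed, and the tables' pairing was run as an alternative.

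The files do not pair the gene IDs with names. The gene table given for cattle, with 37063 genes, matched 0 of the IDs. So 25 gene lists fixed before the data were examined (lipid synthesis and oxidation, muscle fibre types, insulin signalling, markers of fat, blood, immune and other cells, and others) could not be tested, and no gene is named or described by function. The rule for the genes given by ID was also fixed before the data were examined: where fewer than 5 genes passed in a comparison, the 5 with the smallest p were taken, and of IDs without a name at most 2 higher and 2 lower were printed, as values that did not pass. This gave 19 distinct IDs in 7 comparisons. Where an alternative called 5 genes or fewer, those it called are also given, and these were chosen after their values were seen.

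Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10), which left 13219 genes holding 99.97% of all counts. Libraries were scaled by TMM. One robust quasi-likelihood fit (edgeR 4.0.16, R 4.3.3) with a mean per group over all 14 animals had 10 residual degrees of freedom and a common biological coefficient of variation of 0.4145. Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to a common TMM-adjusted library total, computed here from the deposited counts, as mean ± SD over animals, and fold changes are on the log2 scale with their standard error (SE). The 7 comparisons were diet within each breed, breed within each diet, the difference of the diet effect between breeds, and diet and breed averaged over the other factor.

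The test was tried on simulated counts with the means, spread and totals of these animals, in which 100 genes were changed 2-fold and 100 were changed 4-fold. Of the genes changed 4-fold it called 55 for diet in Bonsmara, 65 for diet in Nguni, 60 for breed on the high energy diet, 43 for breed on the low energy diet, 82 for diet averaged over breeds and 86 for breed averaged over diets. Of the genes changed 2-fold it called 8, 8, 11, 4, 34 and 22 in the same order. A difference of 2-fold in a single gene would therefore mostly have been missed in these animals, and a count of 0 does not show that no gene differed. For the difference of the diet effect between breeds, with the genes changed in Nguni on high energy alone, it called 14 of the genes changed 4-fold and 2 of those changed 2-fold, so its count of 0 excludes least. At most 5 unchanged genes were called in any of the 7 comparisons. The genes were simulated independently of each other, so variation shared across genes, as between the real animals, was left out. The numbers called may therefore differ in the real counts.

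Alternatives fixed before the data were examined were DESeq2 1.42.0 (Wald test), limma 3.58.1 (voom with quality weights), DESeq2 size factors in place of TMM, no filter or a mean of at least 10 counts, only the 2 groups compared, 1 surrogate variable (sva 3.50.0), other thresholds, each library as a replicate, the animal as a random block, the title suffix as a block, and leaving out each animal in turn. Alternatives added after the data were seen were the tables' pairing of N1 and N11, fits without libraries that stood apart, libraries thinned to equal totals, the share of counts in the 10 most abundant genes as a covariate, and limma voom on libraries with no block. Library checks used log2(CPM + 1) of 11199 genes with a mean of at least 10 counts. Tests on distances and correlations between animals used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.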

Results

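Gene expression was measured by RNA sequencing in the Longissimus dorsi of Nguni and Bonsmara bulls finished for 120 days on a high or a low energy feedlot diet. The Nguni is an indigenous Sanga breed of southern Africa, and the Bonsmara is a breed with Sanga ancestry. Counts were analysed for 3 Bonsmara bulls on the low energy diet, 3 Bonsmara bulls on the high energy diet, 3 Nguni bulls on the low energy diet and 5 Nguni bulls on the high energy diet, each with 3 libraries. Libraries held 8156040 to 78224599 counts, and the summed libraries of an animal held 34456677 to 101757197. One library, B6_1, supplied 76.9% of the counts of its animal. Of the 20791 genes listed, 2637 had a count of 0 in every library. The number of genes with at least 1 count was 15444 ± 129 (SD, n = 3) in Bonsmara on low energy, 15734 ± 129 (n = 3) in Bonsmara on high energy, 15283 ± 909 (n = 3) in Nguni on low energy and 15406 ± 444 (n = 5) in Nguni on high energy. The 10 most abundant genes were ranked by counts summed over all libraries and were the same 10 for every animal. They took 35.5 ± 7.3%, 39.6 ± 5.1%, 32.8 ± 5.1% and 31.6 ± 5.3% of the counts of an animal in the same order.

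Libraries of one animal were more alike than libraries of different animals. Across genes, log2 CPM correlated with a median Pearson's r of 0.980 within animals, 0.954 between animals of one group and 0.951 between groups, where genes are not independent replicates. Over genes, the median intraclass correlation of libraries within animals was 0.46, so libraries of an animal were not treated as independent. Libraries N008_3 and N215_2 stood apart from all others. They correlated with each other at r = 0.967, and with the remaining libraries of their own animals at 0.901 to 0.907 and 0.888 to 0.892. In N008_3, 305 genes were at least 8-fold above the other libraries of the same animal, and in N215_2 there were 361, against a median of 1 and a highest value of 12 in the other libraries. N008 was in the high energy and N215 in the low energy Nguni group, so this feature entered both sides of the diet comparison in Nguni and 1 side of each comparison between breeds.

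**Figure D1:**
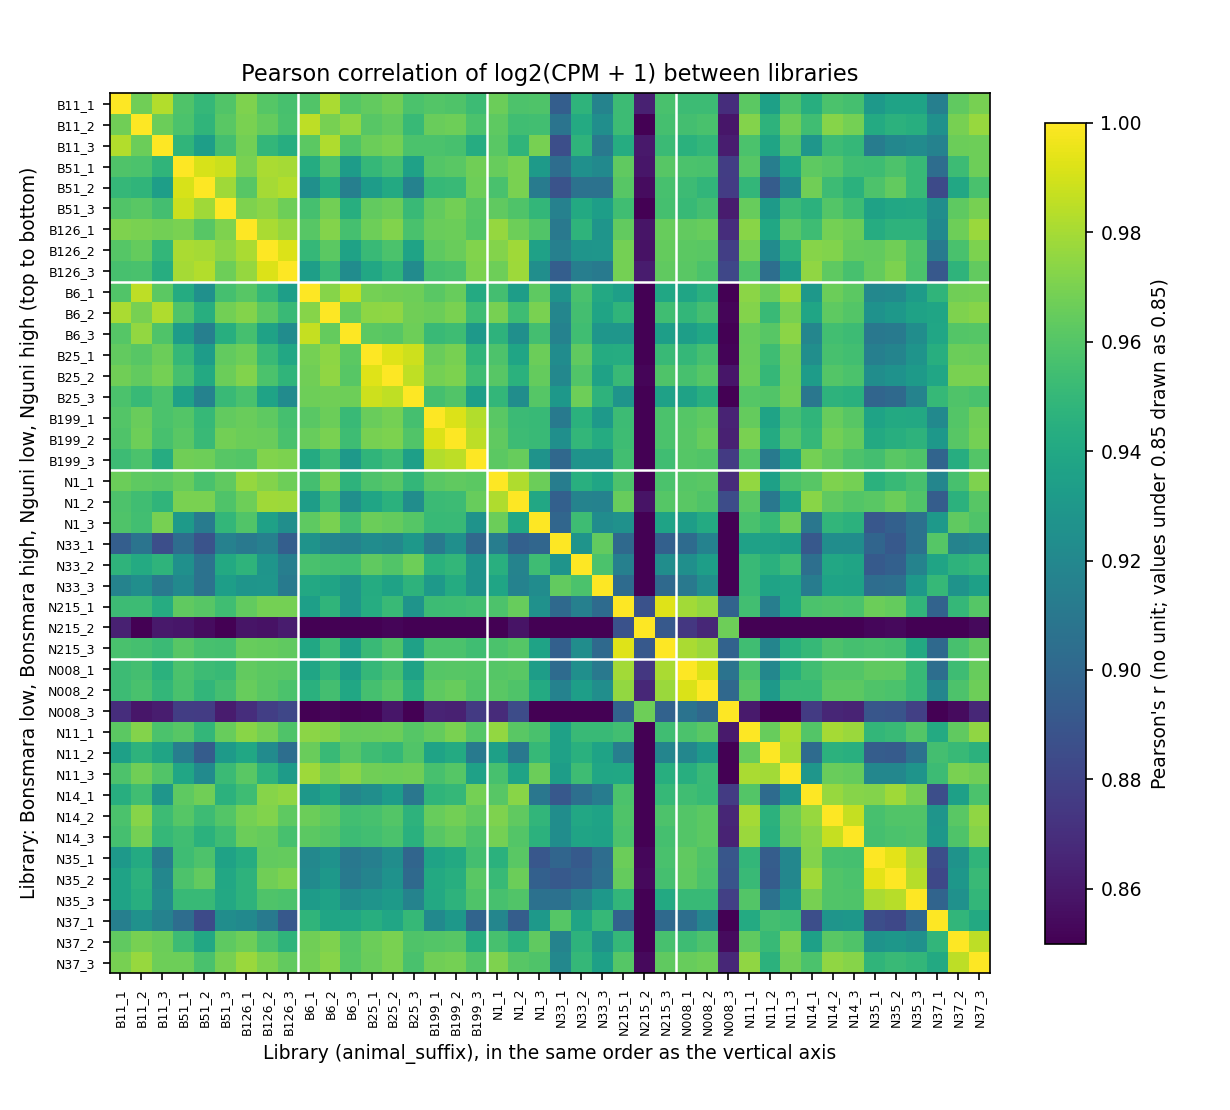
Pearson's r of log2(CPM + 1) between the 42 libraries, with white lines between the groups in the order Bonsmara low, Bonsmara high, Nguni low and Nguni high energy. Squares of 3 libraries along the diagonal are single animals, and the dark bands are libraries N215_2 and N008_3, which correlated with each other at 0.967.

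Among the animals, the first principal component held 32.8% of the variance and the second 14.6%. The animals N008 and N215 lay at 91.5 and 82.1 on the first component, and the next highest animal, N35, lay at 25.3. Breed accounted for 9.86% of the variance between animals, against a median of 7.35% when breeds were exchanged among animals of the same diet (exact permutation test, 1120 arrangements, p = 0.215). Diet accounted for 5.61%, against a median of 6.75% when diets were exchanged among animals of the same breed (exact permutation test, 1120 arrangements, p = 0.692). Neither p was under 0.05, which does not show that breed or diet has no effect. The tests used all libraries and were not repeated without N008_3 and N215_2. Both tests were chosen after the data were seen.

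**Figure D2:**
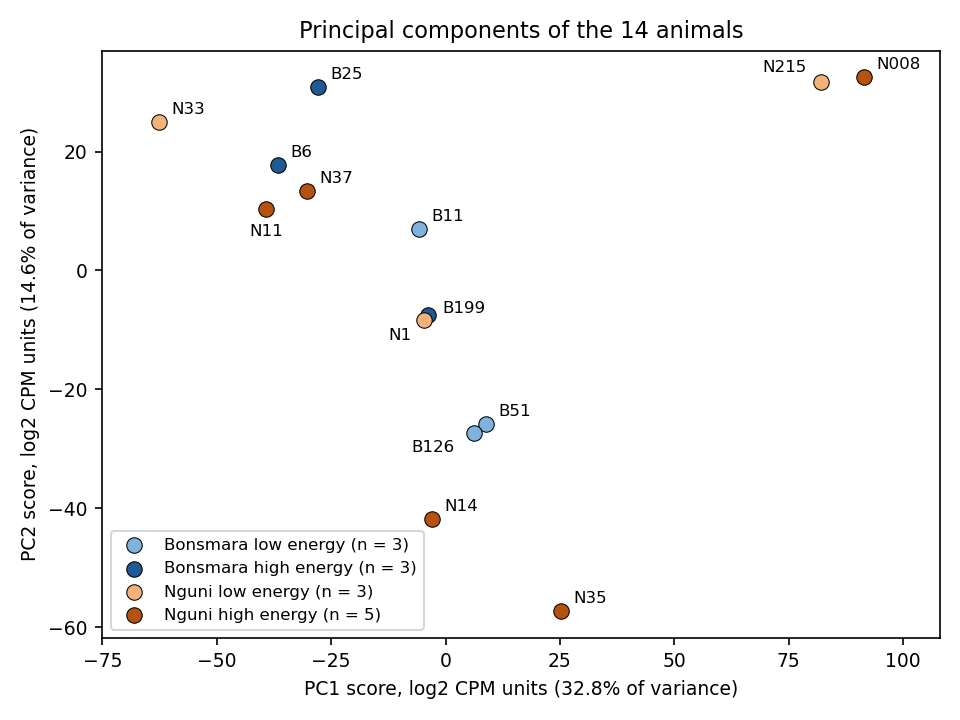
Scores of the 14 animals on the first 2 principal components of log2 CPM, coloured by breed and diet, with 1 point per animal. The groups overlap, and N215 and N008 lie at 82.1 and 91.5 on the first component, away from the other animals.

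The comparison of diets in Bonsmara addressed how dietary energy affects muscle expression in this breed. The gene ENSBTAG00000001058 had 136 ± 12 CPM on high energy against 74.3 ± 12.7 on low energy (SD, n = 3 each), a log2 fold change of 0.87 (SE 0.22, edgeR adjusted p = 0.888), with all 3 animals on high energy above all 3 on low energy. ENSBTAG00000003177 had 4.43 ± 0.41 CPM on high energy and 20.65 ± 17.96 on low energy (log2 fold change -2.22, SE 0.54, adjusted p = 0.888). The low energy mean rested on values of 5.25 to 40.4, with a log2 fold change of -1.29 without B51. ENSBTAG00000038893 had 0 CPM in all 3 animals on high energy and 0 to 0.366 CPM on low energy. None of these passed the adjustment for 13219 genes. The edgeR test called 0 genes, with 508 at an unadjusted p under 0.05 where 661 are expected with no difference, and DESeq2 called 2, of which ENSBTAG00000045987 had counts in 1 and ENSBTAG00000047768 in 2 of the 3 animals on high energy and both were at 0 on low energy. The number at an unadjusted p under 0.05 was 191, 219 and 286 without B51, B126 and B25, and 996 and 809 without B11 and N33. It was 3415 in limma voom with quality weights (smallest adjusted p = 0.0655), 1870 with 1 surrogate variable and 1672 with only the 2 groups compared, and each of these fits called 0 genes. The median absolute log2 fold change over genes was 0.30, and the median SE was 0.39.

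In Nguni, the breed named in the study's title, the same contrast of diets was measured in 5 and 3 animals. ENSBTAG00000030483 had 0.679 ± 0.296 CPM on high energy (n = 5) against 0.137 ± 0.088 on low energy (n = 3), a log2 fold change of 2.33 (SE 0.56, adjusted p = 1), and its 5 values on high energy, 0.407 to 1.02, lay above the 3 on low energy. This separation was lost with N1 and N11 placed as the deposited tables pair them, where its log2 fold change was 0.35 (edgeR adjusted p = 0.946). ENSBTAG00000012208 had 0.906 ± 0.576 CPM on high energy and 5.30 ± 3.84 on low energy (log2 fold change -2.55, SE 0.58, adjusted p = 1), with log2 fold changes of -1.77 without N33 and -1.86 with the tables' pairing. ENSBTAG00000027962 was at 0 CPM in 4 of the 5 animals on high energy and at 0.0428 in the other, against 0.0231, 2.31 and 2.83 CPM on low energy. The edgeR test called 0 genes, with 400 at an unadjusted p under 0.05 where 661 are expected, and DESeq2 called 1, ENSBTAG00000045987, with counts in 3 of the 5 animals on high energy. The edgeR count of 0 stood with the 2 libraries that stood apart removed (484 genes at an unadjusted p under 0.05), and with N1 and N11 placed as the deposited tables pair them (676 genes). Without N008, N215 or N33 the number at an unadjusted p under 0.05 was 986, 962 or 603, and in limma voom with quality weights it was 987, with 0 genes called. It fell to 293 without N35 and to 241 with only the 2 groups compared.

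Breeds were compared on the high energy diet in 5 Nguni and 3 Bonsmara bulls. ENSBTAG00000023600 had 12.5 ± 1.7 CPM in Nguni and 31.5 ± 9.0 in Bonsmara, a log2 fold change of -1.33 (SE 0.22, adjusted p = 0.237), and all 5 Nguni, at 10.35 to 14.33 CPM, lay below all 3 Bonsmara, at 22.8 to 40.8. ENSBTAG00000000905 had 0.110 ± 0.059 CPM in Nguni and 1.09 ± 0.43 in Bonsmara (log2 fold change -3.28, SE 0.56, adjusted p = 0.237). ENSBTAG00000002858 had 1.84 ± 0.83 CPM in Nguni and 0.293 ± 0.101 in Bonsmara (log2 fold change 2.64, SE 0.54, adjusted p = 0.457). ENSBTAG00000038893 had 0.487 ± 0.151 CPM in the 5 Nguni and 0 in all 3 Bonsmara, and its adjusted p was 0.367. The edgeR test called 0 genes, with 1154 at an unadjusted p under 0.05 (533 higher and 621 lower in Nguni) where 661 are expected, and DESeq2 called 27 (9 higher and 18 lower). All 4 genes named above were among the DESeq2 calls, with an adjusted p of 0.000776 for ENSBTAG00000023600 and 0.000944 for each of the others. In limma voom on libraries with the animal as a random block, ENSBTAG00000023600 (adjusted p = 0.00183) and ENSBTAG00000002858 (0.018) were among 44 genes called. ENSBTAG00000000905 and ENSBTAG00000038893 were not tested in that fit, as the low-count filter on libraries removed them. Limma voom with quality weights called 0, with 2207 at an unadjusted p under 0.05. Over all alternatives, the adjusted p of these 4 genes ran from 3.29e-07 to 0.998. The lowest was that of ENSBTAG00000023600 in edgeR with each library as a replicate, which treats the libraries of an animal as independent. The 1154 genes fell to 537 without B25 and to 528 with the share of the 10 most abundant genes as a covariate, both under the 661 expected, and were 723 without B6 and 739 without N35. They rose to 1649 without N11, 1626 without N37 and 1508 without N33. With 1 surrogate variable they rose to 2400, with 0 genes called. Without animal N37, edgeR called 1 gene, ENSBTAG00000034077 (adjusted p = 0.0223, and 0.557 with N37), at 0 to 0.0857 CPM in the other 4 Nguni, 4.04 in N37 and 3.83 to 6.88 in Bonsmara. This gene was chosen after its values were seen.

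On the low energy diet 3 bulls of each breed were compared. ENSBTAG00000023823 had 34.1 ± 23.2 CPM in Nguni and 9.08 ± 2.27 in Bonsmara (log2 fold change 1.91, SE 0.49, adjusted p = 0.956), with all 3 Nguni, at 19.3 to 60.9 CPM, above all 3 Bonsmara, at 7.08 to 11.6. Without N33, the animal at 60.9 CPM, its log2 fold change was 1.18. ENSBTAG00000017661 had 24.7 ± 25.6 CPM in Nguni, from values of 3.88, 16.9 and 53.3, and 3.75 ± 0.69 in Bonsmara (log2 fold change 2.72, SE 0.67, adjusted p = 0.956), with log2 fold changes of 1.47 without N1 and 1.23 with the tables' pairing of N1 and N11. ENSBTAG00000006896 had 7.37 ± 1.73 CPM in Nguni and 16.7 ± 5.5 in Bonsmara (log2 fold change -1.18, SE 0.30, adjusted p = 0.956). ENSBTAG00000017528 had 0.281 ± 0.197 CPM in Nguni and 3.68 ± 3.73 in Bonsmara (log2 fold change -3.69, SE 0.95, adjusted p = 0.956), from Bonsmara values of 0.833, 2.30 and 7.90, with log2 fold changes of -2.47 without B51, the highest of these, and -4.46 without N1. The edgeR test called 0 genes, with 478 at an unadjusted p under 0.05 where 661 are expected, and DESeq2 called 1, ENSBTAG00000047768, at 0, 3.93 and 123.5 CPM in Nguni and 0 in all 3 Bonsmara. The 478 genes were 205 and 294 without B51 and B126, 982 and 1045 without N1 and N215, and 1170 with the tables' pairing. Limma voom with quality weights had 1198 at an unadjusted p under 0.05 and a fit with 1 surrogate variable 739, and both called 0.

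The difference of the diet effect between breeds was tested as the interaction in the same fit. ENSBTAG00000000744 had 18.7 ± 6.2 CPM on high energy (n = 5) and 10.3 ± 1.1 on low energy (n = 3) in Nguni, against 9.40 ± 1.12 on high energy and 17.6 ± 2.5 on low energy in Bonsmara (n = 3 each), a log2 difference of effects of 1.76 (SE 0.39, adjusted p = 0.855). ENSBTAG00000013842 had the same order of means, with 5.22 ± 0.94 and 3.47 ± 0.93 CPM in Nguni and 2.78 ± 0.46 and 5.03 ± 0.74 in Bonsmara (log2 difference 1.44, SE 0.37, adjusted p = 0.855). ENSBTAG00000023600 had the opposite order, with 12.5 ± 1.7 on high and 22.5 ± 4.8 on low energy in Nguni and 31.5 ± 9.0 and 19.8 ± 4.7 in Bonsmara (log2 difference -1.52, SE 0.34, adjusted p = 0.855). ENSBTAG00000019115 had 13.5 ± 2.5 and 21.7 ± 7.0 CPM in Nguni and 25.9 ± 6.2 and 15.02 ± 3.38 in Bonsmara (log2 difference -1.47, SE 0.38, adjusted p = 0.855). The edgeR test called 0 genes, with 552 at an unadjusted p under 0.05 where 661 are expected, and DESeq2 called 0. Leaving out single animals moved the 552 genes to between 261 (without B126) and 1330 (without N215), and they were also over 661 without N11 (880), B11 (862), N37 (773), N008 (747), B199 (746) and N1 (682). Limma voom with quality weights had 1986, a fit with 1 surrogate variable 1387, and the tables' pairing of N1 and N11 1618, and all of these called 0.

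With diet averaged over both breeds, ENSBTAG00000001058 had 136 ± 12 and 137 ± 10 CPM on high energy in Bonsmara and Nguni against 74.3 ± 12.7 and 102 ± 28 on low energy (log2 fold change 0.65, SE 0.14, edgeR adjusted p = 0.999). ENSBTAG00000012850 had 0.741 ± 0.346 and 1.17 ± 0.37 CPM on high energy against 0.316 ± 0.171 and 0.359 ± 0.136 on low energy (log2 fold change 1.48, SE 0.36, adjusted p = 0.999), with a log2 fold change of 0.77 under the tables' pairing of N1 and N11. ENSBTAG00000015127 had 9.87 ± 6.02 and 8.87 ± 2.69 CPM on high energy against 19.7 ± 4.1 and 20.5 ± 5.6 on low energy (log2 fold change -1.11, SE 0.26, adjusted p = 0.999), with a log2 fold change of -0.54 under the same pairing, where N1 was at 26.96 and N11 at 6.42 CPM. ENSBTAG00000012208 had a log2 fold change of -1.90 (SE 0.45, adjusted p = 0.999). The test called 0 genes, with 434 at an unadjusted p under 0.05 where 661 are expected, and DESeq2 called 1, again ENSBTAG00000045987. The 434 genes were 1111 without N33, 810 without N008, 283 without B126, 240 without B51 and 163 with the tables' pairing. Limma voom with quality weights had 2017 at an unadjusted p under 0.05 and a fit with 1 surrogate variable 1080, and both called 0. Across genes, the diet effects in the breeds, which share no animals, correlated at Pearson's r = -0.058 and Spearman's rho = -0.159, and 43.5% of genes had the same sign. Among the 56 arrangements of the Nguni animals, r was at least as high in 36 (exact permutation test, one-sided p = 0.643).

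With breed averaged over both diets, ENSBTAG00000038439 had 50.8 ± 4.4 CPM in Nguni on high energy and 56.2 ± 9.4 on low energy, against 76.2 ± 5.2 and 85.6 ± 2.0 in Bonsmara (log2 fold change -0.60, SE 0.12, edgeR adjusted p = 0.569). All 8 Nguni values, at most 66.9 CPM, lay below all 6 Bonsmara values, at least 70.9 CPM. ENSBTAG00000000905 had a log2 fold change of -2.09 (SE 0.42, adjusted p = 0.569) and ENSBTAG00000002858 one of 1.91 (SE 0.38, adjusted p = 0.569). ENSBTAG00000038893 was detected in all 8 Nguni, at 0.159 to 0.639 CPM, and in 2 of the 6 Bonsmara, at 0.116 and 0.366 CPM (adjusted p = 0.569). The test called 0 genes, with 1144 at an unadjusted p under 0.05 (646 higher and 498 lower in Nguni) where 661 are expected, and DESeq2 called 14. All 4 genes named above were among the DESeq2 calls, at adjusted p of 0.000914 for ENSBTAG00000038439, 0.00266 for ENSBTAG00000002858, 0.00494 for ENSBTAG00000038893 and 0.0132 for ENSBTAG00000000905. ENSBTAG00000038439 and ENSBTAG00000002858 were among 16 genes called in limma voom on libraries with the animal as a random block (adjusted p = 0.0374 each). ENSBTAG00000000905 and ENSBTAG00000038893 were not tested in that fit, as the low-count filter on libraries removed them. ENSBTAG00000038439 was among 2 genes called in limma voom with quality weights (adjusted p = 0.0471). The adjusted p of the 4 genes ran from 1.18e-05 to 0.766 over all alternatives. The lowest came from limma voom on libraries with no block, which treats the libraries of an animal as independent. Without animal N37, edgeR called 1 gene, again ENSBTAG00000034077 (adjusted p = 0.00283, and 0.569 with N37). Across genes, the breed effects on the high and the low energy diet, which share no animals, correlated at Pearson's r = 0.385 and Spearman's rho = 0.117, and 51.9% of genes had the same sign. Among the 56 arrangements of the animals on high energy, r was at least as high in 17 (exact permutation test, one-sided p = 0.304).

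**Figure D3:**
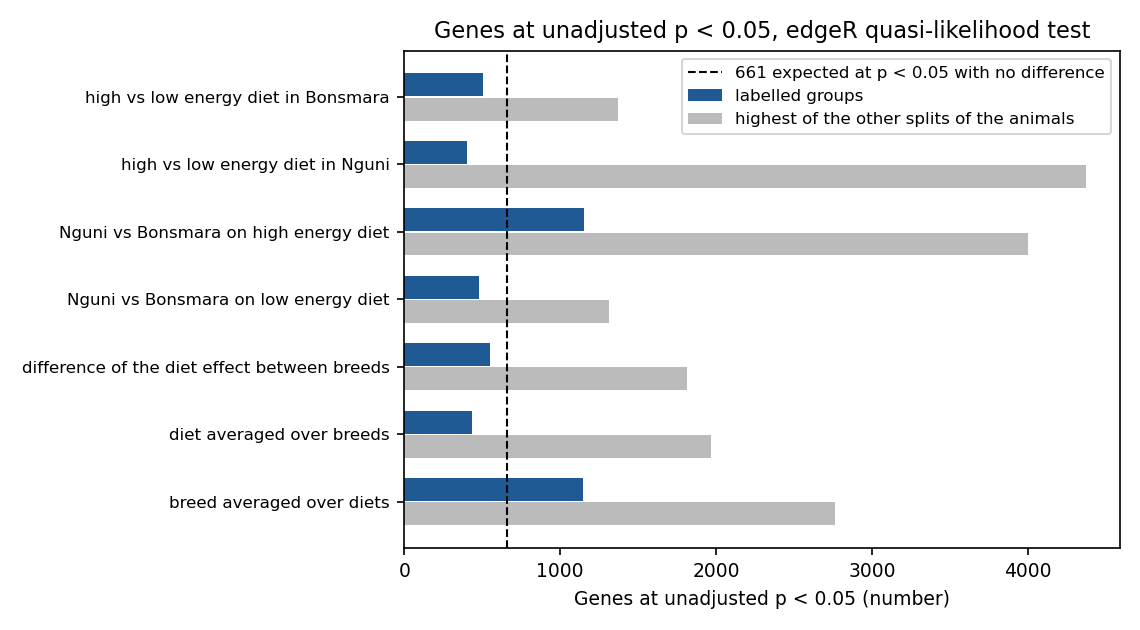
Number of genes at an unadjusted p under 0.05 in the edgeR test for each comparison (blue), and the highest number among the other splits of the same animals (grey). The dashed line marks the 661 genes expected with no difference, and in each comparison the highest other split exceeds the labelled groups.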

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

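Of the tests on patterns of libraries in this part, the ranking of exchanges of B6_2 and B11_2, the placement of N008_3 and N215_2 by animal, and the positions of libraries in place were chosen after the results were seen.

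Single values far from the rest of their group, by Dixon's ratio, were the total of library B126_2, at 18088539 counts against 10196620 to 14172031 in the other libraries of Bonsmara on low energy, and the total of library B6_1, at 78224599 against 9989464 to 24271882 in Bonsmara on high energy. These were 2 of 30 groups of values, where chance alone gives about 1.5 (1 in 20). That count does not weigh how far a value lay, and the ratio was 0.791 for B6_1 and 0.496 for B126_2. Groups of 3 animals and the 15 libraries of Nguni on high energy were not screened. The ratio also marked ENSBTAG00000027962 in animal N35, at 0.0428 CPM where the other Nguni on high energy were at 0, but with all other values at 0 any value above 0 gives the highest possible ratio, so this decides nothing.

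Libraries N008_3 and N215_2 shared 272 of their genes at least 8-fold above their own animals, on the scale of CPM + 1, where 9.83 would be shared by chance, which is 27.7 times as many. Across genes, their log2 differences from their own animals correlated at r = 0.88. The shared genes, chosen for this pattern, took 1.48% and 2.36% of counts in these libraries and at most 0.063% in any other. With all libraries thinned to equal totals, 2 of the 2 still detected more genes than both other libraries of their animal, which argues against depth. By 100 genes that separate animals, chosen without the library placed, 2 of the 2 lay nearest their own animal, which argues against a library of another animal. RNA of another tissue or cell type in both is consistent with the 27.7-fold sharing and stays open, but without gene names the source could not be identified, and no biological explanation was tested.

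Libraries B6_2 and B11_2 each lay nearest the other one's animal: B6_2 correlated at 0.981 and 0.982 with B11_1 and B11_3 and at 0.973 and 0.965 with B6_1 and B6_3, and B11_2 at 0.985 and 0.976 with B6_1 and B6_3 and at 0.967 and 0.966 with B11_1 and B11_3. Of the 42 libraries, 39 lay nearest their own animal (3 by chance). Among libraries of animals other than B6 and B11, 19 of 20 simulated exchanges were found, so the method was not tried on these 2 animals. The third exception was B6_3, nearest N11 (distance 0.631, and 0.664 to its own animal). At equal totals B6_3 lay nearest B11 and B11_1 nearest B6, so the placement of other libraries of these 2 animals was not firm either. With equal totals 0 of the 2 lay nearest their own animal, which argues against depth. An exchange of the 2 libraries ranked 5 of 819 by the gain in correlation within animals, behind 4 exchanges that involve N008_3 or N215_2, and 1 of the 742 without those, so it stays open. On a scale from 0 (own animal) to 1 (the other animal), B6_2 lay at 0.878 and B11_2 at 0.581, where libraries of other animals lay at a median of 0.085 (95% between -0.22 and 0.48), so an exchange and a mixture of RNA cannot be told apart. B6 and B11 are in different diet groups, and with both libraries left out edgeR still called 0 genes for diet in Bonsmara (663 at an unadjusted p under 0.05, DESeq2 2 with all libraries).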

How the results depend on the processing

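The tables' pairing of N1 and N11, thinning, the covariate for the most abundant genes, limma voom on libraries with no block and the fits without libraries that stood apart were added after the data were seen. With edgeR and the animal as replicate, 191 of 193 alternative counts of called genes were 0. These include a threshold on the fold change in each of the 7 comparisons, which had to give 0 because the main fit called 0. Leaving out each animal in turn gave 0 to 1 for breed on high energy and for breed averaged over diets, with the 1 reached without N37, and 0 for the other 5 comparisons. Counts at an unadjusted p under 0.05 then ranged from 191 to 1649. In the order diet in Bonsmara, diet in Nguni, breed on high energy, breed on low energy, interaction, diet averaged and breed averaged, DESeq2 called 2, 1, 27, 1, 0, 1 and 14 genes, with 2957 to 5751 adjusted p not given. With 1 surrogate variable edgeR called 0, with 1870, 589, 2400, 739, 1387, 1080 and 1632 at an unadjusted p under 0.05. The covariate for the most abundant genes gave 300, 430, 528, 697, 319, 402 and 996, and leaving out libraries N008_3, N215_2, B6_2 and B11_2 gave 850, 448, 1161, 678, 589, 725 and 1123, again with 0 called. Limma voom with quality weights called 2 for breed averaged (ENSBTAG00000034077 and ENSBTAG00000038439) and 0 otherwise. The cause of these differences was not tested.

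With each library as a replicate, edgeR called 87, 150, 965, 265, 103, 146 and 1231 genes, which treats 3 libraries of one animal as independent. With the animal as a random block (limma, within-animal correlation 0.458), 44 were called for breed on high energy (41 of them among the 965), 1 for breed on low energy (ENSBTAG00000034077) and 16 for breed averaged (15 among the 1231), and 0 otherwise. In limma voom on libraries with no block 170, 136, 1443, 116, 133, 124 and 1098 were called, and these held all 44, 1 and 16. A replicate block on the title suffix, at the level of libraries, gave 59, 116, 874, 189, 70, 114 and 1036. This fit has no term for the animal, so it too treats the libraries of an animal as independent. Sharing a suffix did not regularly go with a higher correlation: over 18 pairs with the same suffix r was -0.43 to 0.59, and 3 exceeded 0.1. The median was -0.14 with the same suffix and 0.04 with different suffixes. Deviations from a group's mean were used, which cancel over its suffixes, and N008_3 and N215_2 were included. A batch by suffix is therefore not excluded.

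The genes given by ID were chosen for a small p in the main fit, and the alternatives reuse the same counts. A change of direction was therefore unlikely, and its absence is no separate support. For these genes, 0 of 790 alternative values changed direction and 68 passed the threshold. Of these, 19 came from edgeR with each library as a replicate, 18 from the suffix block, 18 from limma voom on libraries with no block, 4 with the animal as a random block, 8 from DESeq2 and 1 from limma voom with quality weights. The tests of gene lists and the covariate from fat cell markers were not run, because no table used here pairs the IDs with names. With all libraries thinned to the smallest total, 8156040 counts, edgeR called 0 genes in all 7 comparisons, with 370 to 1133 at an unadjusted p under 0.05.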

Other observations

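The tests on N1 and N11, of shares of variance, and of the number of detected genes, the closeness of N008 and N215, and the interval for the share of the most abundant genes were chosen after the results were seen, as were the limma fit with no block and the gene described first.

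ENSBTAG00000034077 was near 0 in most Nguni and present in every Bonsmara analysed. The 18 Bonsmara libraries of 6 animals held 30 to 314 counts of it (2.15 to 7.58 CPM). The 21 libraries of 7 Nguni held 0 to 7 counts (0 to 0.59 CPM), with 0 counts in 14. The Nguni N37 was the exception, with 39 to 62 counts in its 3 libraries (2.597 to 6.385 CPM), within the range of the Bonsmara. With N37 the edgeR test for breed averaged over diets gave p = 0.0037 and an adjusted p of 0.569, and without N37 an adjusted p of 0.00283 and a log2 fold change of -6.02. All 3 libraries of N37 carried the gene, so a single mixed library does not give this value, and no explanation was tested.

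The count of genes called when each library is taken as a replicate was weighed for breed averaged over diets, at 1231 genes. Among 40 splits of the animals that keep the libraries of an animal together, the labelled one included, 4 gave as many. The highest other split gave 3517 and the median of the other splits was 174, so chance cannot be excluded. In limma voom on libraries, 1098 genes were called with no block and 16 with the animal as a random block, all of them among the 1098 and 15 among the 1231. Dependence between libraries of one animal may account for most of the calls, and a difference between breeds stays open.

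Splits of the animals into groups of the same sizes were compared by the number of genes at an unadjusted p under 0.05. The numbers of splits below include the labelled split itself. For diet in Bonsmara (508 genes) 2 of 10 splits gave as many, with 1369 as the highest other, and for breed on low energy (478) 6 of 10, with 1311, and 10 splits are too few for a share under 0.05. Chance cannot be excluded for diet in Nguni (400), where 43 of 56 splits gave as many and the highest other gave 4371, or for breed on high energy (1154), with 15 of 56 and 4000. The same holds for the interaction (552), with 17 of 50 and 1817, for diet averaged (434), with 24 of 50 and 1967, and for breed averaged (1144), with 9 of 50 and 2766. The split of the Nguni with 4371 genes, N1, N215, N008, N14 and N35 against N33, N11 and N37, crosses diet. It was picked as the highest of the 56. It follows the order of the Nguni on the first principal component, with N33, N11 and N37 at -62.6, -39.2 and -30.2 and the others at -4.70 and above. N008 and N215, which hold the libraries that stood apart, lie on the same side. The component comes from the same counts, so this order is no separate support for a structure of the samples. The 3 animals on the smaller side were the highest of the 14 for ENSBTAG00000047768, at 123.5, 46.6 and 59.1 CPM. The gene was at 13.1 CPM in B25, 3.93 in N1, 1.17 in B6 and 0 in the other 8. It was chosen after its values were seen and comes from the same counts, so it is no separate support either. In 11 of the 56 splits genes passed the adjustment, up to 2137, where the labelled diets gave 0 in edgeR (400 at an unadjusted p under 0.05, DESeq2 1).

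N008 and N215, which stand in different diet groups, were the closest of 91 pairs of animals even without N008_3 and N215_2, with a mean r of 0.978 against 0.974 for the next pair, B51 and B126.

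With N1 and N11 placed as the deposited tables pair them, edgeR called 0 genes in all 7 comparisons. The number at an unadjusted p under 0.05 was then 676 for diet in Nguni, 1170 for breed on low energy, 1618 for the interaction, the highest of the 7, and 163 for diet averaged over breeds, the lowest. DESeq2 was run only with the labelled groups, where it called 0 to 27. Diet as the tables place it accounted for 4.09% of the variance between animals (exact permutation test, 1120 arrangements, p = 0.960), and as labelled for 5.61% (p = 0.692), so neither placement gave a share beyond the spread between animals.

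It was tested whether the first principal component of the animals follows the share of counts in the 10 most abundant genes: Pearson's r was -0.26 over 14 animals (permutation p = 0.370, adjusted over 8 relations 0.493; Spearman's rho -0.49, p = 0.081; r -0.21 without the 2 farthest animals). This lies under the 0.3 set beforehand as evidence against, but its 95% interval, -0.70 to 0.31, reaches past 0.6, so the test decides nothing. With the number of detected genes r was 0.72 (permutation p = 0.004, adjusted 0.016; rho 0.54, p = 0.047; 0.50 without the 2 farthest), but the sign differed between the breeds, at 0.94 in the 8 Nguni (exact permutation p = 0.00074, adjusted 0.0060; rho 0.88) and -0.74 in the 6 Bonsmara (exact permutation p = 0.092, adjusted 0.147; rho -0.66). Detected genes were counted at unequal totals, and B6, with 15871 the most of the Bonsmara, had the largest total. N008 and N215, with 16151 and 16132, hold the libraries that stood apart. The relations were not repeated at equal totals or without those libraries, so the signs do not establish a difference between breeds.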
